A study of Mus musculus with 4 samples.

How the data were processed

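RNA from mouse extraembryonic ectoderm (ExE), the trophoblast tissue that lies next to the epiblast in the early post-implantation embryo, was sequenced at embryonic day 7.5 in 4 libraries. Per the labels, 2 libraries came from Kdm5b siRNA samples and 2 from controls, which the series text describes as given water. Per the labels' protocols, each library was made from about 10 to 20 cells. Complementary DNA was primed with oligo(dT), extended by template switching, sheared by sonication and made into libraries with a Kapa Hyper Prep kit. The labels do not say when the siRNA was given or whether the 2 libraries of a group came from different embryos. The p-values below therefore measure the spread between these libraries, which may be technical in part.

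The submitters' processing notes name HISAT2 2.1.0, featureCounts 1.6.1, edgeR and the mouse build mm9. The notes do not give the role of each tool, and the annotation, strand setting and handling of reads with several matches are not given in the sources used here. The authors deposited a table of whole-number counts per gene symbol, not normalized, with 24391 genes and 1 column per library. The authors also deposited a table of log2 values. All 97564 of them equal log2(CPM + 1) of the count table within 1.000e-05, with CPM the count divided by the column total and scaled by 1e6, so that the 2 tables hold the same measurement. Because the reference annotation used for names and transcript lengths is of another build than mm9, no coordinates are given. Reads of a gene and of an antisense or overlapping gene cannot be told apart without strand, which bears on Xist and its antisense partner Tsix. Genes with near-identical copies are uncertain for the same kind of reason, among them the ribosomal protein genes, which have many pseudogenes, the Rhox genes, the globin genes and Ddx3y with its X-linked homologue.

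The total counts were 21894763 and 27497610 in the siRNA-labelled libraries and 21445212 and 18247308 in the controls. Between 76.8 and 78.2% of the counts from 1 to 99 in a library were even numbers, a pattern that counting both mates of a read pair would give; whether mates were counted separately is not given in the sources used here. A floor of 3 counts per library was used for genes with 0 counts, equal to between 0.105 and 0.170 CPM. Floors and the counting interval of the Gcm1 ratio cover counting error only, and amplified reads without molecular identifiers are not independent molecules. The interval given for Kdm5b came from the edgeR fit and takes in the spread between libraries.

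The 2 libraries of a group were compared to see whether any library had been deposited under both numbers. Their counts differed, with chi-square per degree of freedom of 81.8 in the siRNA pair and 28.9 in the control pair, so neither pair was a repeated deposit. Technical repeats of such small amplified samples would differ from counting noise too, so this does not show that the libraries came from different embryos.

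The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 12533 genes, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit with robust dispersion, glmQLFTest, two-sided) compared siRNA-labelled with control libraries without a covariate, and Benjamini-Hochberg adjusted p below 0.05 was the threshold. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. All log2 fold changes are siRNA-labelled over control with n = 2 libraries per group, and CPM values are scaled by TMM.

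The comparison, its test, 35 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists covered the cell types of the embryo at this stage, imprinted genes, chromatin enzymes, growth, metabolism, stress and signalling. The 33 lists with at least 3 tested members were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Random lists matched on mean expression, 10000 per list, gave percentiles of the medians. The naming rule took Kdm5b, then the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose mean was at least 10 CPM, without predicted genes, and for each list 2 to 4 tested members with the smallest p. In use, 4 were taken from lists past the threshold and 2 from the others.

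The steps were tested on simulated counts with the means and library sizes of this comparison and 200 changed genes. Each gene was drawn with the dispersion that the fitted trend gives at its abundance, without a spread of dispersion between genes. Among 12005 simulated genes kept, the edgeR step recovered 29.8% of 2-fold, 50.7% of 4-fold and 70.1% of 8-fold changes, with 4 false calls among 11812 unchanged genes. The real data may give poorer rates, since dispersions there may vary between genes. Camera with the preset correlation called a list raised 4-fold and no other list, while camera with an estimated correlation did not call the raised list. The simulated genes were drawn independently, so this cannot show whether the preset correlation suits the real lists.

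The alternatives were DESeq2 size factors or library size alone as scaling, no low-count filter, a filter of 50 counts in 2 libraries, non-robust dispersion, the replicate number as a block, each library left out, DESeq2 1.42.0, and limma on the deposited log2 table with pseudocounts of 1 and 0.1. A further 3 were added after seeing the data: counts divided by 2, the ribosomal RNA gene Rn45s left out, and each library's trend with transcript length removed by a lowess offset. Transcript length was the median over protein-coding transcripts of a symbol. On simulated counts with an imposed length trend, that offset cut the false calls from 1325 to 13. Figures were drawn with matplotlib 3.10.9.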

Results

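The transcriptome of mouse extraembryonic ectoderm (ExE) at embryonic day 7.5 was compared between 2 libraries labelled Kdm5b siRNA and 2 control libraries, each made from about 10 to 20 cells. Kdm5b is a demethylase of histone H3K4, and the series concerns altered histone modification in the extraembryonic tissues of embryos made by in vitro fertilization. The libraries held between 18247308 and 27497610 counts, and 13315 and 13954 genes were detected with siRNA against 13192 and 13242 in controls. Across genes, the log2 CPM values of the siRNA pair correlated with Pearson's r = 0.888 and those of the control pair with r = 0.921. Between groups r lay between 0.859 and 0.895, a range that reached above the value of the siRNA pair; genes are not independent replicates.

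Kdm5b transcript was not lower in the siRNA-labelled libraries. It stood at 127 and 120.5 CPM with siRNA (2924 and 3439 counts) and at 104 and 127 CPM in the controls (2122 and 2239 counts). The Kdm5b log2 fold change was 0.10 ± 0.17 (SE, n = 2 per group), with a 95% confidence interval from -0.30 to 0.50 and an edgeR adjusted p of 0.826. Libraries are therefore named by their labels throughout, and each direction below is one between labels, not one tied to a measured loss of Kdm5b. The sign rested on the setting, since the value was -0.05 without control replicate 1 and -0.17 with the transcript-length trend removed.

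Xist, the mesoderm factor T and the endoderm factor Gata4 were among the largest rises in the siRNA-labelled libraries, and the globins Hba-x and Hbb-bh1 among the largest falls. Of 12533 genes tested, 157 were higher and 168 lower past the threshold; 136 of the higher and 27 of the lower genes differed by 2-fold or more. Car3, a carbonic anhydrase, had 0 counts in both controls and 16.5 and 23.7 CPM with siRNA, at least 127-fold higher against the floor of 3 counts per library. Xist, the RNA that silences an X chromosome, rose 32.04-fold (SE 0.40 on the log2 scale). It was followed by T (log2 fold change 4.68 ± 0.52), Gata4 (4.05 ± 0.56), the growth factor receptor Pdgfra (16.02-fold, SE 0.52 on the log2 scale), Hoxb2 (3.68 ± 0.63), Sox7 (3.56 ± 0.63), the haematoendothelial factor Etv2 (3.52 ± 0.53) and Msx1 (3.51 ± 0.55). The amino acid transporter Slc7a8 (3.51 ± 0.52), the aquaporin Aqp3 (3.45 ± 0.65) and the sulfate transporter Slc13a4 (3.35 ± 0.24) completed the 12 largest rises of abundant genes.

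The embryonic alpha-like globin Hba-x showed the deepest fall of abundant genes, from 612 and 169 CPM in the controls to 0 and 0.42 CPM with siRNA. Hbb-bh1, an embryonic beta-like globin, fell by 3.30 ± 0.55 on the log2 scale, the red cell membrane glycoprotein Gypa by 3.26 ± 0.53 and Alad, an enzyme of haem synthesis, by 1.66 ± 0.19. The mitochondrial protein gene Mtfr2 changed by -2.78 ± 0.33, the X-linked homeobox genes Rhox9 and Rhox6 by -2.13 ± 0.31 and -1.89 ± 0.15, the Tead cofactor Vgll1 by -1.79 ± 0.33 and the Y-linked helicase Ddx3y by -1.77 ± 0.22. Irx4 (-1.55 ± 0.29), the RNA export factor Alyref (-1.42 ± 0.24) and the phosphatase subunit Ppp2ca (-1.29 ± 0.15) closed the 12 largest falls. The adjusted p values of these 24 genes were at most 0.0475 in edgeR's quasi-likelihood test. Without 1 library the call ended for Hba-x (without either siRNA library, adjusted p 0.432 and 0.333), Hbb-bh1 (without either control, 0.0888 and 0.455), Vgll1 (0.149 and 0.1004), Alyref (0.116 and 0.0640), Gypa and Sox7 (without control replicate 1, 0.0741 and 0.0529) and Irx4 (without control replicate 2, 0.165), while each fold change kept its sign.

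The number of genes past the threshold depended on single libraries and on the scaling. It was 389 higher and 511 lower without siRNA replicate 1, 641 and 1004 without siRNA replicate 2, and 155 and 34 without control replicate 1. With library size as the only scaling, 150 genes were higher and 39 lower, so that 79.4% of calls were higher against 48.3% with TMM; the median log2 fold change of all tested genes then stood at 0.19 in place of 0.06. At an unadjusted p below 0.05 there were 2530 genes, and in 52.1% of genes the groups did not overlap, where chance gives 33.3% for 2 against 2.

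**Figure D1:**
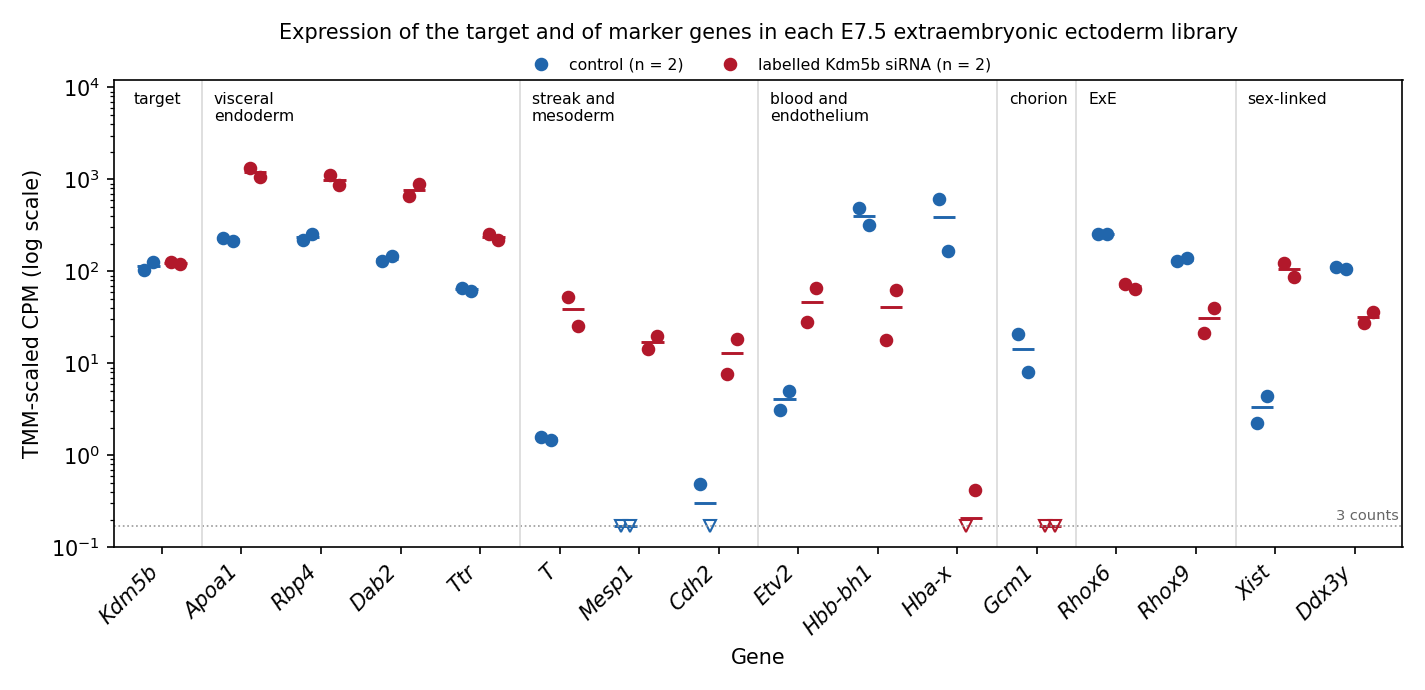
TMM-scaled CPM on a log axis for the target and 15 marker genes in each library; points are libraries, horizontal bars are group means, and open triangles on the dotted line are values under 3 counts per library. Kdm5b lies at 104 to 127 CPM in all 4 libraries, the endoderm genes are higher and Hbb-bh1, Hba-x, Gcm1, Rhox6 and Rhox9 lower in both siRNA-labelled libraries.

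Markers of visceral endoderm, the absorptive epithelium that wraps the early embryo, were higher as a group. Of 20 tested members 13 rose and none fell, 15 rose when adjusted over the list alone, and all 20 fold changes were positive with a median log2 fold change of 2.41. Apoa1, an apolipoprotein, rose 5.40-fold (2.43 ± 0.14), from 230.2 and 216 CPM to 1343 and 1066 CPM. The endocytic adaptor Dab2 rose 5.64-fold (2.49 ± 0.17), the retinol carrier Rbp4 4.16-fold (2.06 ± 0.15) and transthyretin, Ttr, 3.73-fold (1.90 ± 0.16). Each of these 4 had an edgeR adjusted p of at most 0.00575. Camera gave the list an adjusted p of 3.123e-12, and an adjusted p of 0.475 with an estimated correlation. Between 12 and 16 members were past the threshold under every alternative run, and 13 to 15 when any 1 library was left out.

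Genes of the parietal endoderm list were also higher, with 3 of 12 members past the threshold, 6 when adjusted over the list alone, and a median of 1.54. Thbd and Plat of that list had too few counts to be tested, at most 28 and 32 in a library. The list rose in the same libraries as the mesoderm genes below, so it does not by itself identify parietal endoderm cells. Fst, an activin antagonist, had 0 counts in both controls and 22.9 and 10.6 CPM with siRNA, at least 106-fold higher. Pdgfra and Sox7, given above, were the other two; Sparc, a basement membrane protein, stood at 0.77 ± 0.16 with an edgeR adjusted p of 0.0555. The camera adjusted p was 1.655e-04, and with an estimated correlation the adjusted p was 0.475. The count was 8 without siRNA replicate 2.

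Primitive streak and mesoderm genes were higher in the same libraries as the visceral endoderm genes. All 12 tested members had positive fold changes, 3 past the threshold and 9 when adjusted over the list alone, with a median of 3.92, or 3.33 with members at 0 counts set to their bounds. T was at 52.9 and 25.7 CPM with siRNA against 1.57 and 1.48 CPM. Mesp1, a factor of early mesoderm, had 0 counts in both controls and was at least 107-fold higher, and the cadherin Cdh2 rose by 5.36 ± 0.99. Foxf1 stood at 2.69 ± 0.61 with an edgeR adjusted p of 0.0677. Camera gave an adjusted p of 1.204e-05, and 0.475 was the adjusted p with an estimated correlation. Without control replicate 1 the count was 6, without siRNA replicate 2 it was 5, and Cdh2 held its call in 12 of 16 alternatives, missing with library size alone (adjusted p = 0.0507), the replicate block (0.0703), limma at a pseudocount of 0.1 (0.0572) and the length trend removed (0.0571).

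Wnt targets, FGF and ERK targets and Hox genes were higher beside the endoderm and mesoderm markers. Of 10 Wnt targets, 1 was past the threshold, 5 when adjusted over the list alone (median 2.15). It was the Wnt inhibitor Nkd1, at 2.99 ± 0.40, while Axin2 (3.21 ± 0.77), Lgr5 (2.92 ± 0.72) and Lef1 (3.43 ± 0.93) had edgeR adjusted p of 0.0753, 0.0813 and 0.101. Of 12 FGF and ERK targets, 1 rose, 3 when adjusted over the list alone (median 0.87). This was the ERK phosphatase Dusp6, at 1.90 ± 0.28, and Phlda1 stood at 2.61 ± 0.55 (edgeR adjusted p = 0.0576). Among 10 Hox genes Hoxb2 and Hoxb1 rose, also when adjusted over the list alone (median 1.11). Hoxb1 had 0 counts in both controls and 3.79 and 21.7 CPM with siRNA. The mean of these unequal libraries was at least 80.03-fold higher against the floor, a bound that siRNA replicate 1 alone would not reach. The camera adjusted p was 3.389e-04 for Wnt targets, 0.00318 for FGF and ERK targets and 0.0198 for Hox genes, and with an estimated correlation the adjusted p was 0.475, 0.475 and 0.522. Wnt targets called numbered 2 or 3 without any 1 library, and FGF and ERK targets 3 without siRNA replicate 1 or control replicate 2, where their median was 0.69 and 1.49. The Hox median was 4.44 without control replicate 1, 2.07 without siRNA replicate 2 and 1.77 without siRNA replicate 1. The Hox call was lost without control replicate 2 (adjusted p = 0.0561), and 3 Hox genes were called without control replicate 1. Hoxb1 held its call in 12 of 16 alternatives, missing without siRNA replicate 2 (adjusted p = 0.0602), with library size alone (0.0501) and with limma at pseudocounts of 1 and 0.1 (0.0570 and 0.0559).

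The epiblast list did not pass the threshold as a group. None of 15 tested members was past the threshold, nor any when adjusted over the list alone, while DESeq2 called 1 higher and 1 lower. The epiblast list had a median of -0.10, a mean of 0.52 and a camera direction upward (adjusted p = 0.996), so that median and test differed in sign. Its members lay on both sides, with Utf1 at -0.68 ± 0.20 and the Nodal coreceptor Tdgf1 at 3.61 ± 1.06 (edgeR adjusted p 0.120 and 0.121). Without control replicate 2 the median was 0.97 and 3 members were higher, and without siRNA replicate 2 it was -0.32 and 3 members were lower.

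Trophoblast lists did not pass camera's threshold, but single members did. Of 19 tested ExE and trophoblast stem cell genes, none rose and 2 fell, Rhox6 and Rhox9, also when adjusted over the list alone (median -0.16, camera adjusted p = 0.205). Without siRNA replicate 2 that list had 1 higher and 4 lower (median -0.52), and without siRNA replicate 1 it had 1 higher and 2 lower (median 0.02). Gcm1, the factor that drives syncytiotrophoblast formation in the chorion, was nearly absent from the siRNA-labelled libraries, with 1 and 2 counts against 422 and 142 in the controls. That made a ratio of 255 with a 95% counting interval from 86.9 to 1241 (edgeR adjusted p = 0.0212; 0.0659 without control replicate 1). The lactate transporter Slc16a1 of the same 11 chorion and labyrinth genes rose by 0.95 ± 0.11. This list had a median of 0.72 and a mean of -0.55, camera pointing down (adjusted p = 0.950), with 2 higher and 1 lower when adjusted over the list alone. Its median was -0.10 without siRNA replicate 1, 0.38 without control replicate 1 and 0.31 without control replicate 2. Phlda2, an imprinted brake on placental growth, fell by 1.13 ± 0.14 and was the only call in 8 ectoplacental cone and spongiotrophoblast genes, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.950). The median of these genes ran from 0.02 to 0.42 with 1 library left out, and Plac1 stood at 1.12 ± 0.48. Of the 3 trophoblast giant cell genes tested none passed (median 0.01, mean -0.42, camera direction down, adjusted p = 0.99998). Their median ran from -1.12 to 0.31 with 1 library left out.

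Markers of embryonic blood and endothelium moved in opposite directions. Etv2 rose while Hba-x and Hbb-bh1 fell, also when adjusted over the list alone, and the other 11 of 14 tested members did not pass (median -0.02, camera adjusted p = 0.738). Without siRNA replicate 1, 4 members were lower and the median was -0.77, and without siRNA replicate 2 it was 0.53. Of 5 maternal decidua and immune genes tested none passed, also when adjusted over the list alone (median -0.16, camera adjusted p = 0.727). With 1 library left out, which also changed the genes tested, that median ran from -1.47 to 7.04. Lyz2 had 0 counts with siRNA and at most 20 in a control, and Col1a1 stood at 3.46 ± 1.72 (edgeR adjusted p = 0.319). Only 2 of 14 neural ectoderm genes had enough counts to be tested, and neither passed.

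Ribosomal protein genes were lower together by a small amount. Of 75 tested members 28 fell and none rose, 67 fell when adjusted over the list alone, and 74 fold changes were negative with a median of -0.57. Rps14 fell by 0.71 ± 0.09, Rpl19 by 0.62 ± 0.10, Rps11 by 0.61 ± 0.10 and Rpl4 by 0.58 ± 0.08. The nuclear-encoded subunits of oxidative phosphorylation had a median of -0.44 with 2 of 27 members lower, 15 when adjusted over the list alone; these were Cox4i1 (-0.87 ± 0.12) and cytochrome c, Cycs (-0.65 ± 0.12). Camera gave adjusted p of 2.070e-17 and 2.323e-05, and with an estimated correlation the adjusted p was 0.475 for both lists. Short transcripts as a class were lower in the siRNA-labelled libraries, with a median of -0.17 in the shortest and 0.28 in the longest of 3 equal length bins. With that trend removed 3 ribosomal protein genes were called (median -0.41) and 2 of oxidative phosphorylation (median -0.28), and with library size as the scaling 2 and 1. Without control replicate 1 the counts were 1 and 1, without control replicate 2 they were 12 and 2, without siRNA replicate 1 they were 51 and 4, without siRNA replicate 2 they were 59 and 8, and with the replicate number as a block they were 1 and 1; the calls of Rpl4, Rpl19, Rps11 and Cycs ended without control replicate 1 (adjusted p 0.0598, 0.119, 0.127 and 0.199).

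Genes of the unfolded protein and integrated stress response were higher as a list (median 0.44), with none of 19 past the threshold and 9 when adjusted over the list alone. Edem1 and Sel1l, of the degradation pathway for misfolded proteins, stood at 1.01 ± 0.21 and 1.03 ± 0.22, and the chaperones Hsp90b1 and Pdia4 at 0.52 ± 0.12 and 0.45 ± 0.12. Cholesterol synthesis genes had a median of 0.31, with none of 19 past the threshold and 2 when adjusted over the list alone; Dhcr7 stood at 1.56 ± 0.34 and Sqle at 0.69 ± 0.15. The camera adjusted p was 0.00234 and 0.0331, and the adjusted p with an estimated correlation was 0.475 and 0.522. The cholesterol call was lost without siRNA replicate 2 (0.298), control replicate 1 (0.160) or control replicate 2 (0.0793), and with the replicate number as a block (0.0766). DESeq2 called 8 stress response and 2 cholesterol genes higher. Without siRNA replicate 1 the counts were 3 and 2 higher, and without siRNA replicate 2 they were 7 and 4, with 1 stress response gene lower.

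The glucose transporter Slc2a3 rose 3.66-fold (1.87 ± 0.14), from a mean of 645 CPM to one of 2357 CPM, and the fatty acid binding protein Fabp3 fell by 0.97 ± 0.11. Of 15 nutrient transport genes 4 rose and 1 fell, 7 and 2 when adjusted over the list alone (median 0.51, camera adjusted p = 0.0599). The nutrient transport list passed by fry (upward, adjusted p = 0.0316) and by camera in 3 of 16 alternatives, with library size alone (0.0465) and with limma at pseudocounts of 1 and 0.1 (0.0374 and 0.0465). Of 21 glycolysis and hypoxia genes 2 rose and 1 fell, 3 and 6 when adjusted over the list alone (median -0.10, camera adjusted p = 0.421). That median lay at percentile 77.1 of random lists matched on expression, above most of them. The glycolytic enzyme Tpi1 fell by 0.63 ± 0.10, a call that ended without control replicate 1 (adjusted p = 0.0876). Without siRNA replicate 2 the glycolysis and hypoxia count was 2 higher and 9 lower, and without siRNA replicate 1 it was 4 and 5.

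Imprinted genes expressed from the paternal allele were higher as a list, with 1 of 18 past the threshold, also 1 when adjusted over the list alone (median 0.61). This was Peg3, a zinc finger gene, which rose by 1.56 ± 0.23, while Zrsr1 stood at -1.77 ± 0.59, Sfmbt2 at -0.47 ± 0.13 and Dlk1 at 2.22 ± 0.83. The camera adjusted p was 0.0331, and with an estimated correlation the adjusted p was 0.475. Of 13 maternally expressed imprinted genes Meg3, a long noncoding RNA, rose by 2.11 ± 0.36 and Phlda2 fell, with 2 higher and 2 lower when adjusted over the list alone (median 0.15, camera adjusted p = 0.950). The maternal list had 3 higher and 2 lower, and the paternal list 4 higher and 1 lower, without siRNA replicate 2. The paternal list missed the threshold with the stricter filter (0.0574), without siRNA replicate 1 (0.0515), siRNA replicate 2 (0.173) or control replicate 2 (0.0512), and with the length trend removed it and Peg3 did so too (adjusted p 0.0507 and 0.0617).

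Chromatin lists did not pass camera's threshold, though by fry's test for change in either direction the H3K4 enzymes (adjusted p = 0.0302) and Polycomb genes (0.0122) did. That test passed 25 of the 33 lists tested, so a pass is not particular to chromatin lists. Among 19 H3K4 methylation enzymes the methyltransferase gene Kmt2d rose by 1.41 ± 0.23, and its complex partner Ash2l stood at -0.50 ± 0.10 with an edgeR adjusted p of 0.0542; adjusted over the list alone 1 was higher and 1 lower (median 0.19, camera adjusted p = 0.971). Of 25 Polycomb genes, Kdm6b, an H3K27 demethylase, rose by 1.91 ± 0.26 and Pcgf5 fell by 0.99 ± 0.17, also when adjusted over the list alone (median 0.19, camera adjusted p = 0.727). Dnmt3a, a DNA methyltransferase, stood at 1.09 ± 0.26 and Zfp57 at 0.69 ± 0.34; none of 10 DNA methylation enzymes passed, 1 when adjusted over the list alone (median 0.29, camera adjusted p = 0.254). Without control replicate 1 the calls of Kmt2d and Pcgf5 ended (adjusted p 0.0598 and 0.155), and without siRNA replicate 2, 4 Polycomb genes were lower. Without siRNA replicate 1 the medians of the H3K4 and Polycomb lists were -0.12 and -0.06.

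Sex-linked genes split by chromosome. Xist stood at 124 and 87.8 CPM with siRNA against 2.26 and 4.37 CPM in the controls, and Ddx3y at 27.6 and 35.9 CPM against 111 and 107 CPM. Of the 5 genes of this list 1 was higher and 1 lower, 1 and 4 when adjusted over the list alone (median -1.77, camera adjusted p = 0.0559). The list passed in 6 of 16 alternatives, with library size alone (0.0249), no filter (0.0427), the replicate block (0.0482), limma at pseudocounts of 1 and 0.1 (0.0183 and 0.0248) and without siRNA replicate 1 (0.0481), and by fry its adjusted p was 0.108. Without siRNA replicate 2, 3 members were lower.

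Lists of proliferation, p53 and BMP signalling genes did not pass, but single members did. Of 20 mitotic genes Ccnb2, a mitotic cyclin, fell by 0.83 ± 0.12, with 1 higher and 4 lower when adjusted over the list alone (median -0.19, camera adjusted p = 0.183; 0.0229 with the length trend removed), and Birc5 stood at -0.51 ± 0.11. Of 23 DNA replication genes the histone mRNA binding protein Slbp fell by 0.76 ± 0.13, with 1 higher and 4 lower when adjusted over the list alone (median -0.09, camera adjusted p = 0.560), and Pcna stood at -0.59 ± 0.12. Though negative, the mitotic and DNA replication medians lay at percentiles 76.3 and 83.7 of random lists matched on expression. They were thus above most lists of like abundance. Perp was the only call among 17 p53 targets, at 0.88 ± 0.17, with 3 higher and 1 lower when adjusted over the list alone (median 0.25, camera adjusted p = 0.0930), and Bax stood at -0.47 ± 0.12. Among 11 TGF-beta and BMP targets Id1 fell by 1.12 ± 0.15 and Msx1 rose, with 1 higher and 3 lower when adjusted over the list alone (median -0.22, mean 0.03, camera direction down, adjusted p = 0.504). The median of these targets ran from -0.45 to -0.007 with 1 library left out. Without siRNA replicate 2, 6 mitotic genes were lower, 4 DNA replication genes were lower and 2 higher, and 3 TGF-beta and BMP targets were lower. Calls of Slbp and Perp ended without control replicate 1 (adjusted p 0.0938 and 0.122). That of Perp held in 10 of 16 alternatives, and also ended without control replicate 2 (0.154), with DESeq2 size factors (0.0557), with non-robust dispersion (0.0517), with the replicate block (0.0844) and with the length trend removed (0.0580).

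With all 4 libraries, no member passed in the 6 tested interferon genes (median 1.37, camera adjusted p = 0.433), the 14 immediate early genes (median 0.07, 0.920), the 10 germline genes (median 0.01, 0.950) or the 16 epithelial junction and keratin genes (median -0.01, mean 0.07, camera direction down, 0.950). The immediate early median ran from -0.26 to 0.39 with 1 library left out. Adjusted over the list alone, 1 interferon gene was lower, 1 epithelial gene was higher and 2 were lower. DESeq2 called 1 interferon gene higher and 1 lower, 3 immediate early genes higher and 1 lower, 1 epithelial gene higher and 2 lower, and no germline gene. Without siRNA replicate 2, 4 epithelial, 1 immediate early, 1 germline and 1 interferon gene were lower and 2 immediate early genes higher, and the germline median was -1.08. Without siRNA replicate 1, 1 germline gene was higher and 1 interferon gene lower, and without control replicate 2, 1 immediate early gene was higher. Bst2 stood at -1.10 ± 0.25, Stat1 at 1.34 ± 0.70, Egr1 at 1.17 ± 0.34, Klf6 at 0.48 ± 0.14, Dazl at 2.71 ± 1.02, Stk31 at -0.53 ± 0.40, Epcam at -0.45 ± 0.12 and Ocln at 1.90 ± 0.52. Genes encoded in the mitochondrial genome were not analysed here.

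Over the 33 lists tested, 9 were higher and 2 lower past camera's threshold with its preset correlation. Against random lists matched on expression, the Hox and cholesterol medians lay at percentiles 96.2 and 96.24, so they stood out less. The other lists called higher lay at 99.54 or above. Ribosomal proteins lay at 0 and oxidative phosphorylation at 0.29. None of the 33 lists passed with an estimated correlation, where the smallest adjusted p was 0.475. That setting also missed a simulated 4-fold rise of the visceral endoderm list. Genes were drawn independently in that simulation, so it cannot tell which correlation suits these lists. The paternally expressed imprinted list had an estimated correlation of -0.0446, below the preset 0.01, yet its unadjusted camera p went from 0.0110 to 0.111. The other lists past the threshold had estimates from 0.0162 to 0.185. A miss under this setting thus need not come from correlated members, and with 2 libraries per group it does not show that a list is unchanged. By fry, which tests whether a list moves on balance in 1 direction, 6 lists passed (visceral endoderm, primitive streak and mesoderm, ribosomal proteins, stress response, paternally expressed imprinted and nutrient transport), and 25 passed its test for change in either direction.

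**Figure D2:**
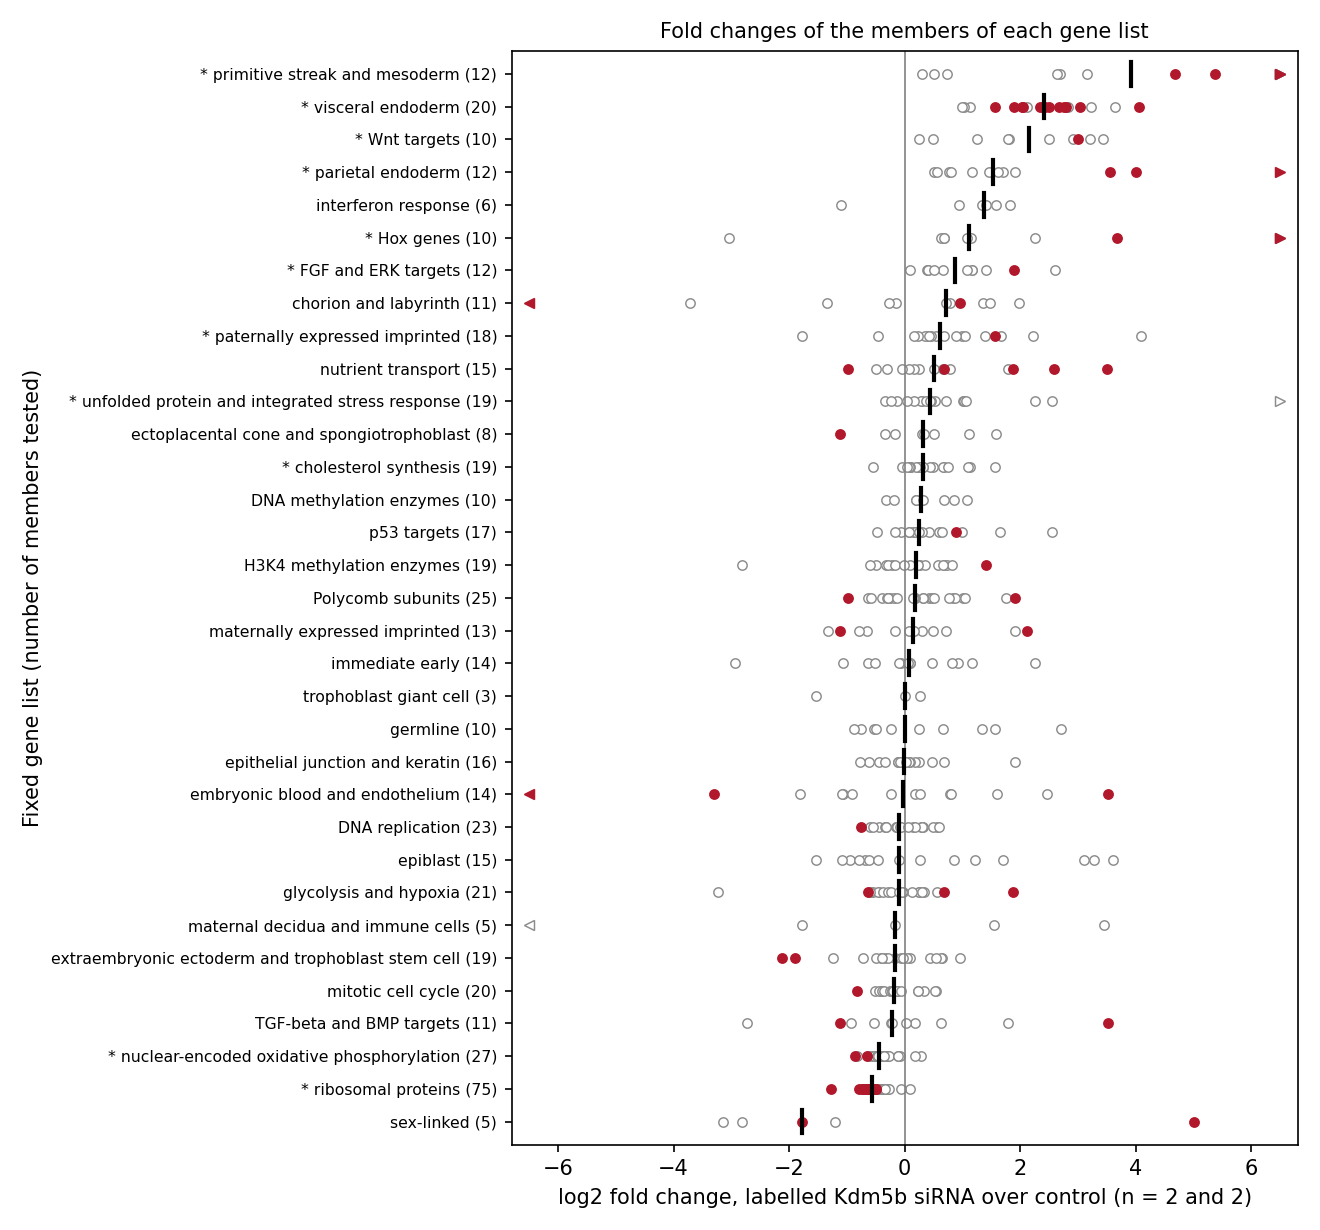
Log2 fold change, libraries labelled Kdm5b siRNA over controls, of each tested member of the 33 lists; each point is a gene, filled red where the edgeR adjusted p was below 0.05, black bars are list medians, triangles mark members beyond the axis, and an asterisk marks lists past camera's threshold. Medians run from -1.77 for the sex-linked list to 3.92 for primitive streak and mesoderm, with visceral endoderm at 2.41 and ribosomal proteins at -0.57.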

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

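The counts of genes and lists, the fixed lists and the named genes were recomputed under 16 alternatives, fewer where a gene or list had too few counts in one, and the symbol families under 7. Of these, the halved counts, the removal of Rn45s and the length correction were chosen after seeing the data. Genes higher numbered 703 with no low-count filter, 266 with the stricter filter, 675 with DESeq2 and 259 with limma at a pseudocount of 1. Genes lower numbered 731, 307, 723 and 98 under the same 4 settings, 49 with limma at a pseudocount of 0.1, 39 with library size alone and 264 with halved counts. The unfiltered, strictly filtered, DESeq2 and halved-count settings kept all 157 and 168 calls. With 1 library left out, the lone library of its group is assumed to vary like the other group; genes higher ran from 155 to 641 and genes lower from 34 to 1004. Without control replicate 1, 92 of the higher and 25 of the lower calls were shared. For the Kdm5b log2 fold change, values ran from -0.047 to 0.22 with 1 library left out, and the length correction gave -0.17; adjusted p lay between 0.481 and 0.974 over all alternatives. The epiblast list median was 0.0265 with library size alone, 0.22 with no filter, 0.10 with the stricter filter, 0.0255 and 0.0752 with limma at pseudocounts of 1 and 0.1, and from -0.32 to 0.97 with 1 library left out. The cause of these shifts was not tested, except that the filters change the number of genes tested. Lists past the threshold ran from 8 to 12 with 1 library left out, and numbered 0 with an estimated correlation and 6 by fry. The length correction called 122 genes higher and 118 lower, of which 117 and 81 were shared, and 11 lists, of which 10 were shared.

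Libraries with the same replicate number did not deviate together. The correlation of their deviations was 0.003 across 12533 genes and -0.05 across 7738 genes of at least 10 CPM. This gave no sign of pairing but does not exclude a shared litter or day. A fit with the replicate block called 107 genes higher and 36 lower, and gave an epiblast list median of 0.0131.

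Of 55 named genes past the threshold, no alternative turned the direction of any; the number still past it was lowest, 40, without control replicate 1, then 42 with the replicate block and 43 with library size alone. Calls held in 10 of 16 alternatives for Vgll1 and Perp, 11 for Irx4, Alyref, Cycs and Rps11, 12 for Cdh2, Hoxb1, Pcgf5 and Rpl19, 13 for Sox7, Slbp and Tpi1, 14 for Aqp3, Hba-x, Hbb-bh1, Gypa and Rpl4, and 15 for Kmt2d, Gcm1 and Peg3; the other named calls held in all 16. A design of 2 against 2 cannot go below p = 0.333 in an exact permutation test. The common biological coefficient of variation was 0.520. In the simulation, which used the dispersion trend alone, 29.8% of 2-fold changes were recovered. Genes short of the threshold therefore cannot be taken as unchanged.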

Other observations

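Families taken by gene symbol after the values were seen, 6 in all, added other groups to the fixed lists; symbols that match a family's pattern but name no member were left out. Cathepsins, the lysosomal proteases, were higher, with 5 of 10 past the threshold: Ctsh (2.30 ± 0.18), Ctsc (1.34 ± 0.17), Ctsl (1.26 ± 0.15), Ctsb (1.20 ± 0.11) and Ctsz (0.87 ± 0.14). Solute carriers were higher in 15 of 230 and lower in none (median 0.35), among them the glucose transporter Slc2a2 (2.32 ± 0.31) and the glutamine transporter Slc1a5 (1.97 ± 0.26). Proteasome subunits had a median of -0.49 with 6 of 37 lower, translation initiation factors a median of -0.40 with none of 42 past the threshold, and Rhox homeobox genes a median of -1.85 with 2 of 12 lower. Camera adjusted p over the 6 families ran from 9.204e-15 to 0.00265, and with an estimated correlation the adjusted p ran from 0.166 to 0.245. Neither adjustment allows for choosing the families after their values were seen. Each median kept its sign under the 3 scalings, with the length trend removed and without each library. Counts rested on single libraries: 25 proteasome genes were lower and 1 higher without siRNA replicate 2, 15 lower without siRNA replicate 1 and 0 without control replicate 1. Without siRNA replicate 2, 22 initiation factors were lower and 2 higher, and 23 solute carriers were higher and 5 lower. Solute carriers higher and lower numbered 19 and 1 without siRNA replicate 1, 12 and 1 without control replicate 2, and 10 and 0 without control replicate 1.

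The tests of the visceral endoderm and Y-linked patterns and of mitochondrial ribosomal proteins were chosen after a result was seen, for the last the lower level of 1 member, Mrpl45; those of transcript length and chromosome share were written down before.

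Visceral endoderm markers rose together in both siRNA-labelled libraries. A lower share of ExE cells would raise the markers of other cell types. The rise was not alike in all of them. The visceral endoderm median exceeded that of embryonic blood and endothelium by 2.44 on the log2 scale. The 95% bootstrap interval over members was 1.39 to 3.74, and the range with 1 library left out was 1.74 to 2.90. That comparison was chosen after a result was seen, and members of the blood list went both ways. It therefore does not exclude a lower ExE share. Other lists were less clear, with a difference of 2.51 (0.872 to 3.33) from the epiblast list and 0.88 (-0.48 to 1.72) from parietal endoderm, and primitive streak and mesoderm genes had a median of 3.92. A larger share of visceral endoderm cells stays open as a candidate explanation, since with 10 to 20 cells per library a few cells may be enough. Of 16 abundant markers 14 (87.5%) lay within 1 log2 unit of their median, with a full range of 1.12 to 4.05. A joint change of these genes within cells could pass that wide window too, so it does not favour a cell share. A change within the ExE cells linked to the siRNA label also stays open and untested.

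Ribosomal protein genes were lower by a median of -0.57. Random lists matched on length and expression together had a median of -0.32. Transcript length, expression level or both may therefore account for at least part of the fall, and these lists cannot separate the 2. Of these lists 0 of 10000 (0%) reached -0.57, the lowest being -0.49. They drew genes independently, however, while the ribosomal protein genes had an estimated inter-gene correlation of 0.18. Their spread may thus be too narrow to exclude length and expression level as the whole cause. For oxidative phosphorylation, 4.27% of matched lists lay as low, between the bounds set for either verdict. By this test length, expression level and a change of its own cannot be told apart. With the length trend removed, camera with its preset correlation still gave adjusted p of 3.875e-11 for ribosomal proteins and 0.00671 for oxidative phosphorylation (medians -0.41 and -0.28). Mitochondrial ribosomal proteins, a family taken up after Mrpl45 was seen to be lower, had a median of -0.50 with 5 of 77 lower (camera adjusted p = 9.204e-15; 0.166 with an estimated correlation). That count was 16 without siRNA replicate 1, 37 without siRNA replicate 2 and 1 without control replicate 1. The length trend itself followed the groups, the longest of 3 equal bins of genes exceeding the shortest by 0.37 and 0.13 in the siRNA-labelled libraries and by -0.25 and -0.17 in the controls, so that a difference in RNA or cDNA quality may underlie it.

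Xist was higher and 4 of 4 tested Y-linked genes were lower in both siRNA-labelled libraries than in both controls. Besides Ddx3y these were Eif2s3y (-3.14 ± 0.75), Kdm5d (-2.82 ± 0.96) and Uty (-1.21 ± 0.40), named after their values were seen. A different mix of male and female embryos between the groups would give this pattern and stays open as a candidate explanation. These genes are the pattern itself, so they are no separate test of it. Such a mix would differ along with the siRNA label, so sex and label could not be told apart in the other results. Direct sex chromosome dosage is argued against as the source of most calls, because 306 of the 325 called genes lay on autosomes. The share of calls on X or Y was 5.85%, against 3.92% of tested genes. An indirect effect of sex on autosomal genes was not tested.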
